A study of Mus musculus with 16 samples.

How the data were processed

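The series holds 16 samples: 6 untreated 5C libraries, 4 siRNA 5C libraries, and 3 CTCF ChIP-seq libraries with 3 inputs. Groups and replicate numbers were taken from sample titles. For the control siRNA libraries the growth text conflicts with the title, and the title was used. Tests, thresholds, the rule for named window pairs and most alternatives were chosen before the data were examined.

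The deposited 5C tables give raw read counts per pair of primers, made by the authors. Bowtie and mm9 are named in the submitters' processing notes, with no version. Filters on reads are not given in the sources used here. Per the labels' protocols, templates were HindIII 3C libraries, and those of the siRNA experiment were made in situ. Reads of the untreated 5C libraries are those of earlier samples, per the labels. Of the counts of the untreated libraries, 0.16% to 0.79% came from primers of the same orientation and were left out, as were counts between loci and those outside the authors' bins. The siRNA tables list only forward-reverse pairs within 2 loci. A single Oct4 primer pair held 2.30% to 6.75% of all counts of an untreated library.

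The authors' deposited interaction scores are given per pair of 4 kb bins and per library, and the deposited classified table sorts 3942 looping pixels into 7 looping classes, with 1820 background pixels. The scale of the score is not given in the sources used here. A further 45 per-sample columns of these files were not used. The classified table writes Oct4 as a date-like name, which was read as Oct4. Primer coordinates of the siRNA experiment differed from the other list by at most 1 bp.

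CTCF peaks were called by the authors with MACS2 on mm9, per the submitters' processing notes. The deposited lists give a fold enrichment (a ratio over local background) and the −log10 q per peak, which are the authors' values and were used only to describe, rank or filter peaks within a list. Peak names point to a single library per list, not a pool. File names speak of downsampled reads, and the inputs were not analysed here.

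Counts of forward-reverse pairs within a locus were summed over pairs of 16 kb windows, each fragment placed by its midpoint, which used 91509 primer pairs in the untreated libraries and 32660 in the siRNA libraries. Pairs of windows were tested with edgeR 4.0.16 (quasi-likelihood test, filterByExpr defaults, TMM factors) in R 4.3.3. An offset per library and locus came from a loess trend (span 0.5) of log count plus 0.5 on distance. The untreated libraries shared 1 fit and the siRNA libraries another, with group as the only term and a Benjamini-Hochberg adjusted p below 0.05 as the threshold. Common biological coefficients of variation were 0.201 and 0.381. Libraries of the same group differed by a chi-square per degree of freedom of 17.0 to 19.4 in the untreated groups, 43.5 for control siRNA and 96.1 for YY1 siRNA, so no library was a duplicate of another.

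A window pair took the looping class with most pixels in it, and 20 ties were left out. Classes were tested with camera (preset correlation 0.01) and fry from limma 3.58.1. DESeq2 1.42.0 was an alternative tool. Mean deposited scores per class and library were compared by an exact permutation test. Peaks were compared with bedtools 2.31.1 at an overlap of at least 1 bp. Anchor bins of 4 kb were tested by shifting peaks circularly within each locus 10000 times, adjusting over all classes and kinds of site. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

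Named window pairs were, per comparison and locus, those past the threshold, at least 3 windows apart and with separated libraries, taking the 2 with the largest rise and the 2 with the largest fall. The first of each is given in the text. Values for target genes' own windows are not given, because no annotation of mm9 was used here. For a group with 0 counts the fold is a lower bound against 3 counts over the group, and for 1 to 3 counts the ratio carries a 95% exact (Clopper-Pearson) interval.

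The steps were tested on simulated data. For NPCs against ES cells in 2i, over 15021 pairs, 48 of 100 pairs changed by a log2 fold change of 1 and 82 of 99 changed by 2 were recovered, and 7.14% of calls were false. For the siRNA comparison, over 3585 pairs, 30 of 99 and 65 of 97 were recovered, and 3.06% of calls were false. A class of 60 pairs, simulated as independent with a fall of 0.3 on the log2 scale in the siRNA comparison, had a median of -0.31 and was called by camera, and in NPCs against ES cells in 2i such a class had -0.47 and was called. Over 20 further classes of this kind the mean of the medians was -0.29 (SD 0.082) in the siRNA comparison, with 19 called at an unadjusted p below 0.05, and -0.33 (SD 0.031) in NPCs against 2i, with 20 called, so the single value of -0.47 lay outside their range of -0.38 to -0.25.

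Alternatives were plain TMM scaling, a single distance trend, DESeq2, other count filters, windows of 8 kb and 32 kb, single primer pairs, windows at least 3 apart, a replicate block, each library left out, and other libraries in the fit. For classes, an estimated correlation and another rule for class membership were tried. For CTCF, a stricter q, reciprocal overlap of 50%, equal list sizes and wider bins were tried. Libraries were also thinned to 7158647 counts in 10 draws, and single primer pairs inside class pixels were tested, both chosen after seeing the data.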

Results

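Chromosome contacts at 7 mouse loci were counted by 5C, an assay that amplifies ligation products between chosen restriction fragments with alternating forward and reverse primers. The loci were named for Sox2, Nanog, Oct4 and Klf4 (transcription factors of pluripotent cells, Sox2 also of neural progenitors), for Nestin and Olig1-Olig2 (genes of neural progenitors and of the oligodendrocyte lineage), and for a gene desert. V6.5 mouse embryonic stem (ES) cells were grown either in 2i, a serum-free medium with LIF and 2 kinase inhibitors, or in serum with LIF. Neural progenitor cells (NPCs) came from newborn mouse brain and were grown as neurospheres. Each of these 3 untreated groups had 2 libraries. NPCs treated with siRNA against YY1, a zinc-finger DNA-binding protein, or with control siRNA gave 2 libraries each, covering the Sox2 and Klf4 loci only. Per the labels, the siRNA-treated cells were plated at a lower density than the untreated NPCs. CTCF, the DNA-binding protein found at many loop anchors, was mapped by ChIP-seq with 1 library per untreated condition.

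Total 5C counts were 11784821 and 14201950 for ES cells in 2i, 26533530 and 25791222 for ES cells in serum, and 14887963 and 14698138 for NPCs. The control siRNA libraries held 5792078 and 6251316 counts, and the YY1 siRNA libraries 4419309 and 12993781. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these libraries. Counts are PCR reads without molecular identifiers, so intervals on single window pairs cover counting error only. NPCs came from mice carrying a Sox2-eGFP allele and ES cells from another line, so cell type and origin cannot be separated in any comparison of NPCs with ES cells. Contacts were summed over pairs of 16 kb windows, and window positions are given in mm9 without gene annotation.

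The first question was how contacts differ between NPCs and ground-state ES cells. In NPCs against ES cells in 2i, 1208 window pairs rose and 1349 fell among 15190 tested, which was 16.8% of pairs. The Sox2 locus had the highest share, with 29.0% of 1888 pairs changed, followed by Nanog with 23.0% of 944. The Olig1-Olig2, Klf4, Nestin and Oct4 loci followed, with 18.0% of pairs changed in Olig1-Olig2, 17.7% in Klf4, 268 of 2056 pairs in Nestin and 12.8% in Oct4. None of the 62 gene desert pairs passed edgeR's test.

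The Olig1-Olig2 pair with the largest rise joined windows starting at 91190613 and 91254613 on chromosome 16, 64 kb apart. Its log2 fold change was 2.72 with SE 0.17 (edgeR adjusted p = 9.0e-07, 2 libraries per group), it belonged to the authors' NPC only looping class, and neither window held a CTCF peak. In the Nestin locus, windows starting at 87765088 and 88021088 on chromosome 3 rose by a log2 fold change of 2.75 with SE 0.24 (edgeR adjusted p = 6.0e-06). That pair also belonged to the NPC only class, its first window held 2 CTCF sites present in all 3 lists, and its second window 1 site of the ES lists only. In the Sox2 locus, contacts between windows starting at 34124880 and 35004880 on chromosome 3 rose by 2.44 on the log2 scale. Klf4 windows starting at 54931979 and 55779979 on chromosome 4 rose by 2.59, and Nanog windows starting at 122301360 and 122877360 on chromosome 6 by 2.08 (edgeR adjusted p = 0.00076, 0.0020 and 0.046 for these Sox2, Klf4 and Nanog pairs).

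The largest falls were at long range and rested on few counts. The Oct4 pair of windows starting at 35614392 and 36318392 on chromosome 17, in the 2i only class, had a log2 fold change of -4.81 with SE 0.75 (edgeR adjusted p = 0.00051). The Klf4 pair starting at 55395979 and 55667979 on chromosome 4, also in the 2i only class, had 2 counts over both NPC libraries and was 29.5 times lower (95% exact interval 7.91 to 247). The Olig1-Olig2 pair starting at 90630613 and 91126613 had 0 counts in both NPC libraries and was at least 9.03-fold lower, taking 3 counts over the group as the floor, although the authors' table placed pixels of this window pair in the 2i and NPC class. The Sox2, Nanog and Nestin pairs with the largest falls had log2 fold changes of -3.36, -2.41 and -3.28 (edgeR adjusted p = 0.012, 0.041 and 0.035). In the Oct4 locus, windows starting at 36014392 and 36238392 rose 40.4 times from a single count in the 2i libraries (95% exact interval 6.59 to 1662, edgeR adjusted p = 0.019). The Nanog and Oct4 rises and the Sox2, Nanog and Nestin falls no longer passed edgeR's test without replicate 1 of ES cells in 2i (adjusted p from 0.073 to 0.20) or without replicate 2 of NPCs (0.058 to 0.39). All of these but the Sox2 fall also ended without replicate 2 in 2i (0.084 to 0.21). The Nanog fall ended without replicate 1 or 2 in serum (0.053 and 0.059), and the Nanog rise without replicate 2 in serum (0.058) and with the libraries of both groups alone (0.054). Leaving out a library leaves its group with 1, which is assumed to vary like the other groups, so a call can end through fewer libraries alone.

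By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4609 pairs had an unadjusted p below 0.05, and the libraries of both groups were fully separated in 56.4% of pairs against 33.3% by chance. Without replicate 1 of ES cells in 2i, 1220 pairs changed. In 8 kb windows 1471 pairs rose and 2000 fell (8.79% of those tested), and over single primer pairs 1049 rose and 2157 fell (4.21%). The per-locus distance trend removes any shift common to a whole locus, and without it the directions within loci moved. With plain scaling, 650 Sox2 pairs rose and 148 fell in place of 274 each, 25 Nanog pairs rose and 319 fell in place of 93 and 124, and 441 Olig1-Olig2 pairs rose and 100 fell in place of 249 and 182. In Oct4, 235 rose and 856 fell in place of 307 and 466, in Nestin 132 rose and 197 fell in place of 139 and 129, and 24 gene desert pairs rose in place of 0. Sox2 then still had the highest share of changed pairs (42.3%), followed by the gene desert (38.7%) and Nanog (36.4%).

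The second comparison set NPCs against ES cells in serum, the medium in which cells are less uniform than in 2i. In NPCs, 2120 pairs rose and 2199 fell, 28.4% of those tested. Sox2 and Olig1-Olig2 had the highest shares, 35.4% and 35.2%, followed by Nanog with 31.1%, Nestin with 27.4%, Oct4 with 26.4% and Klf4 with 18.9%. In the gene desert 22.6% of pairs changed, 9 upward and 5 downward, so the control locus was not free of calls. This order depended on the scaling, since with plain scaling the gene desert (43.5%) and Nanog (40.1%) lay above Sox2 (35.3%) and Olig1-Olig2 (33.4%).

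The Sox2 pair with the largest rise joined windows starting at 34268880 and 34540880, 272 kb apart, with a log2 fold change of 2.82 and SE 0.22 (edgeR adjusted p = 8.4e-07). It belonged to the NPC only class, and its second window held 1 CTCF peak present in all 3 lists. Rises in Nanog (windows starting at 122621360 and 122893360), Klf4 (55027979 and 55571979), Nestin (87413088 and 88277088) and Olig1-Olig2 (90614613 and 91734613) had log2 fold changes of 2.42, 2.20, 3.68 and 3.20 (edgeR adjusted p = 0.012, 0.019, 0.0067 and 0.0083). Falls in Sox2 (34124880 and 34876880), Nanog (122301360 and 122765360) and Nestin (87349088 and 87941088) had values of -2.69, -2.78 and -2.17 (edgeR adjusted p = 0.0047, 0.00032 and 0.016). The gene desert pairs with the largest changes had log2 fold changes of 0.79 (windows starting at 133420809 and 133484809 on chromosome 5) and -0.86 (133404809 and 133484809).

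Oct4 windows starting at 34782392 and 35310392 rose 59.3 times from a single count in serum (95% exact interval 9.63 to 2442), and those starting at 34974392 and 35790392 were 22.7 times lower with a single count in NPCs (3.89 to 917). Against 0 counts in NPCs, the Klf4 pair starting at 55299979 and 55667979 was at least 5.39-fold lower, and the Olig1-Olig2 pair starting at 90630613 and 91126613 at least 8.78-fold lower.

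Without replicate 1 in serum, the Nanog and Klf4 rises and the Oct4, Nestin and gene desert falls no longer passed edgeR's test (adjusted p from 0.079 to 0.17). Without replicate 2 in serum, the Klf4, Nestin, Olig1-Olig2 and gene desert rises ended (0.066 to 0.096). Without replicate 1 of NPCs, the Nanog, Klf4 and Olig1-Olig2 rises and the Klf4 and Nestin falls ended (0.050 to 0.12), and without replicate 2 of NPCs the Oct4, Klf4, Nestin and gene desert falls (0.059 to 0.11). With plain scaling the Nestin and gene desert falls ended in edgeR (0.054 and 0.053), with DESeq2's size factors these and the Oct4 fall (0.055 to 0.064), and with a common distance trend the gene desert fall (0.074).

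In this comparison 6025 pairs had an unadjusted p below 0.05 in edgeR, and 64.9% were separated against 33.3% by chance. Without replicate 1 or replicate 2 of ES cells in serum, 2332 or 2122 pairs changed. With plain scaling, rising and falling pairs numbered 73 and 306 in Nanog in place of 132 and 162, 87 and 355 in Klf4 in place of 156 and 187, and 491 and 96 in Nestin in place of 287 and 277. In Olig1-Olig2 they numbered 495 and 304 in place of 435 and 406, and in the gene desert 27 and 0 in place of 9 and 5.

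The third comparison asked how the medium alone changes contacts in ES cells. In serum against 2i, 1516 pairs rose and 1615 fell, 20.6% of those tested. The shares were close to each other in the 6 gene loci, from 19.6% in Olig1-Olig2 and 20.0% in Nestin to 20.5% in Sox2, 21.1% in Oct4 and Klf4 and 21.2% in Nanog. In the gene desert 12.9% changed. With plain scaling the shares of the 6 gene loci lay further apart, from 20.2% in Olig1-Olig2 to 28.9% in Nestin and 29.5% in Sox2, and the gene desert had 17.7%.

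The largest rise was in the Oct4 locus, between windows starting at 34942392 and 35902392, 960 kb apart. Its log2 fold change was 3.72 with SE 0.31 (edgeR adjusted p = 9.7e-06), from 316 and 688 counts in 2i to 8681 and 14498 in serum, and the authors' table placed it in the constitutive class. A single primer pair held 96.8% of its counts. Rises in Sox2 (34124880 and 34876880), Nanog (122301360 and 122877360), Klf4 (55059979 and 55667979), Nestin (87493088 and 88149088) and Olig1-Olig2 (90662613 and 91622613) had log2 fold changes of 2.52, 2.19, 2.02, 2.23 and 1.84 (edgeR adjusted p = 0.011, 0.029, 0.049, 8.0e-05 and 0.0018). Falls in Sox2 (34812880 and 35020880, in the 2i only class), Nanog (122637360 and 122797360), Klf4 (55363979 and 55875979), Nestin (87349088 and 88277088) and Olig1-Olig2 (91126613 and 91670613) had values of -2.57, -2.77, -3.39, -4.20 and -2.74 (edgeR adjusted p = 0.0031, 0.00013, 0.0076, 0.017 and 0.0014). Oct4 windows starting at 34782392 and 35310392 were 55.5 times lower, with a single count in serum (95% exact interval 9.29 to 2258). The gene desert pairs with the largest changes had values of 0.80 and -0.89.

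Without replicate 1 in 2i, the Nanog and Klf4 rises, the Oct4 fall and both gene desert changes no longer passed edgeR's test (adjusted p from 0.052 to 0.23). Without replicate 2 in 2i, the Sox2, Nanog and Klf4 rises and the Klf4 and Nestin falls ended (0.066 to 0.27). Without replicate 1 in serum, the Sox2 and Klf4 rises, the Oct4 and Nestin falls and both gene desert changes ended (0.063 to 0.24). Without replicate 2 in serum, the Nanog, Klf4 and Olig1-Olig2 rises, the Klf4 and Nestin falls and both gene desert changes ended (0.050 to 0.25). The Klf4 rise also ended with DESeq2 on the distance-trend offsets (0.061) and among windows at least 3 apart (0.052). Named pairs were chosen with separated libraries, which nearly fixes their direction when a library is left out. None of the calls that ended with a library left out turned in direction. Among those with more than 3 counts in the lower group, the log2 fold change was then 54.5% to 115% of its full value in NPCs against 2i, 71.9% to 106% in NPCs against serum and 64.3% to 128% in serum against 2i.

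In this comparison 5162 pairs had an unadjusted p below 0.05 in edgeR, and 63.4% were separated against 33.3% by chance. The count was 1239 without replicate 1 of ES cells in 2i, 1261 without replicate 1 in serum and 840 without replicate 2 in serum. With plain scaling, rising and falling pairs numbered 491 and 66 in Sox2 in place of 184 and 203, 49 and 157 in Nanog in place of 96 and 104, and 458 and 786 in Oct4 in place of 616 and 656. They numbered 290 and 142 in Klf4 in place of 169 and 214, 48 and 547 in Nestin in place of 209 and 203, and 304 and 178 in Olig1-Olig2 in place of 239 and 230.

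Across the named window pairs, a single primer pair held over 80% of the counts in 10 of 24 for NPCs against 2i, 8 of 28 for NPCs against serum and 13 of 27 for serum against 2i. In 5, 7 and 7 of these, all counts came from a single primer pair.

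**Figure D1:**
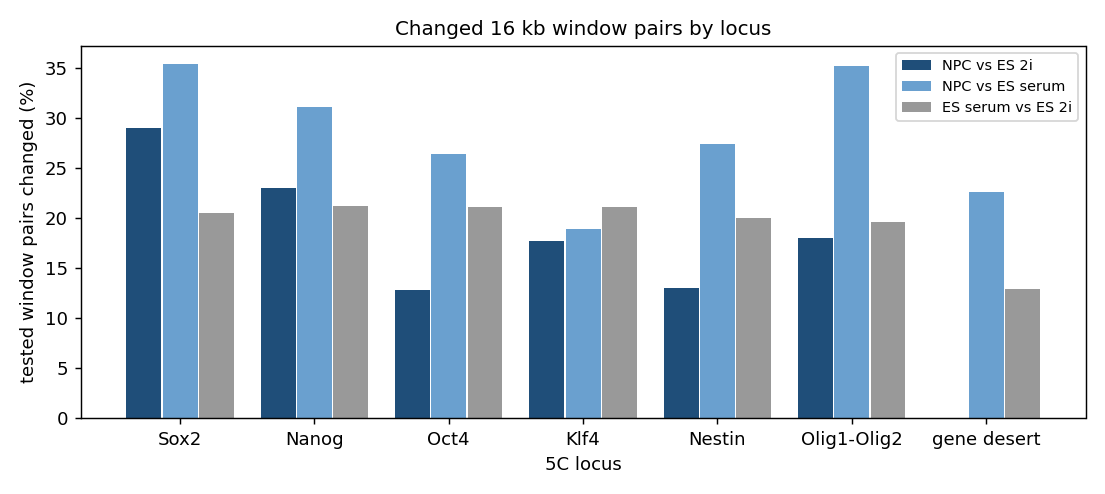
Bars give the percent of tested 16 kb window pairs that changed in each 5C locus, for each of the 3 comparisons of untreated groups. Sox2 has the highest share in NPCs against ES cells in 2i (29.0%), and the gene desert has 0 changed pairs there and 22.6% in NPCs against ES cells in serum.

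The authors sorted looping pixels into classes by the conditions that showed the loop, and most classes named for some of the conditions had median changes in the direction of their names. With camera at a preset correlation, 17 of 24 tests of a class in a comparison passed, and with an estimated correlation 3 passed. In NPCs against 2i, the 2i only class (106 window pairs) had a median log2 fold change of -1.20 and the 2i and serum class (69 pairs) -1.14, while the NPC only class (183 pairs) had 1.03 and the serum and NPC class (27 pairs) 0.47. All 4 passed camera at the preset correlation, and none with an estimated one (adjusted p = 0.056 for 2i only and 0.0504 for the others). The estimated correlations were 0.196 for 2i only, 0.129 for 2i and serum, 0.104 for NPC only and -0.0029 for serum and NPC. The last lies below the preset 0.01, so a higher correlation is not why the serum and NPC call ended. In NPCs against serum, the NPC only class had 1.15 and the 2i and NPC class 0.71, while the serum only class had -0.67 and the 2i and serum class -0.89. With an estimated correlation the NPC only and serum only classes passed (camera adjusted p = 0.041 and 0.026), and the 2i and NPC and the 2i and serum classes did not (adjusted p = 0.080 and 0.081). In serum against 2i, the serum only class had 0.59 and the serum and NPC class 0.42, while the 2i only class had -0.90 and the 2i and NPC class -0.65. With an estimated correlation the serum only class passed (camera adjusted p = 0.016), and the 2i and NPC (adjusted p = 0.058), 2i only and serum and NPC classes (adjusted p = 0.095 for both) did not. The constitutive class had medians of 0.16, 0.12 and 0.03, and background pixels -0.15, -0.12 and -0.09, in the order of the comparisons above. For the serum only class in NPCs against 2i, the median was 0.02 but the mean -0.06, and camera's direction was downward without passing. Camera and fry also called some classes whose names give no difference. In NPCs against 2i, camera called the constitutive class upward (41 pairs rose and 22 fell, adjusted p = 0.012) and background downward (22 rose and 84 fell, adjusted p = 0.0029). With an estimated correlation neither passed camera (adjusted p = 0.11 and 0.10), while both passed fry (adjusted p = 0.032 and 0.0083). In NPCs against serum both passed fry as well (adjusted p = 0.049 and 0.047) but not camera (adjusted p = 0.12 and 0.17). At the preset correlation camera also called the 2i only class downward in NPCs against serum (median -0.22, adjusted p = 0.030), and the 2i and serum class (median -0.26, adjusted p = 0.0042) and the NPC only class (median -0.12, adjusted p = 0.0497) downward in serum against 2i. None of these 3 passed camera with an estimated correlation (adjusted p = 0.50, 0.37 and 0.54) or fry (adjusted p = 0.14, 0.082 and 0.14).

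Several of these values depended on the setting. With plain scaling the serum and NPC class had medians of 0.22 in NPCs against 2i and 0.05 in serum against 2i, where its camera call ended (adjusted p = 0.14). In 8 kb windows the 2i and NPC class had 1.26 in NPCs against serum and -1.07 in serum against 2i, and the 2i and serum class -0.45 in serum against 2i. The 2i only class in NPCs against serum had -0.34 with plain scaling and -0.12 without replicate 1 in serum, and passed fry without either 2i library (adjusted p = 0.0039 and 0.0033). The NPC only class in serum against 2i had -0.27 in 8 kb windows, where camera called it (adjusted p = 0.0063), and -0.21 without replicate 2 in 2i. Its call ended in camera with plain scaling (median -0.02, adjusted p = 0.74) and without any 1 of the 4 libraries in 2i or serum (adjusted p from 0.050 to 0.065), while fry passed without either NPC library (adjusted p = 0.025 and 0.024).

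For NPCs against 2i with plain scaling, camera called neither the constitutive class (median 0.09, adjusted p = 0.11) nor background (adjusted p = 0.087), and fry called background alone (adjusted p = 0.25 and 0.022). The constitutive class also lost fry without either 2i library, either serum library or replicate 1 of NPCs (adjusted p from 0.078 to 0.12), and camera without replicate 2 in 2i (median 0.06, adjusted p = 0.052). Its median without replicate 1 of NPCs was 0.05. Background lost fry without either NPC library (adjusted p = 0.066 and 0.060), and had a median of -0.09 without replicate 2 in 2i. For NPCs against serum, both lost fry with plain scaling (adjusted p = 0.15 and 0.38). The constitutive class lost it in every fit without 1 library except that without replicate 2 of NPCs (adjusted p from 0.075 to 0.23), and background without any 1 of the serum and NPC libraries (adjusted p from 0.14 to 0.17). The constitutive class passed camera there in 8 kb windows (adjusted p = 0.0093), with any pixel counted (adjusted p = 0.037) and without replicate 2 of NPCs (adjusted p = 0.044). Its median there was 0.21 in 8 kb windows and 0.03 without replicate 1 of NPCs, and that of background -0.02 with plain scaling. In serum against 2i, background had -0.05 without replicate 2 in 2i and -0.16 without replicate 2 in serum, and passed camera without replicate 1 in 2i (adjusted p = 0.036).

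The classes were chosen on these same libraries, so their direction is not independent evidence. Of the 183 NPC only pairs, 121 rose and 4 fell against 2i over all pairs tested (136 and 7 adjusted over the list alone), and 144 rose and 2 fell against serum (149 and 2 adjusted over the list alone). Of the 106 2i only pairs, 66 fell and 0 rose in NPCs against 2i (80 and 0 adjusted over the list alone).

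**Figure D2:**
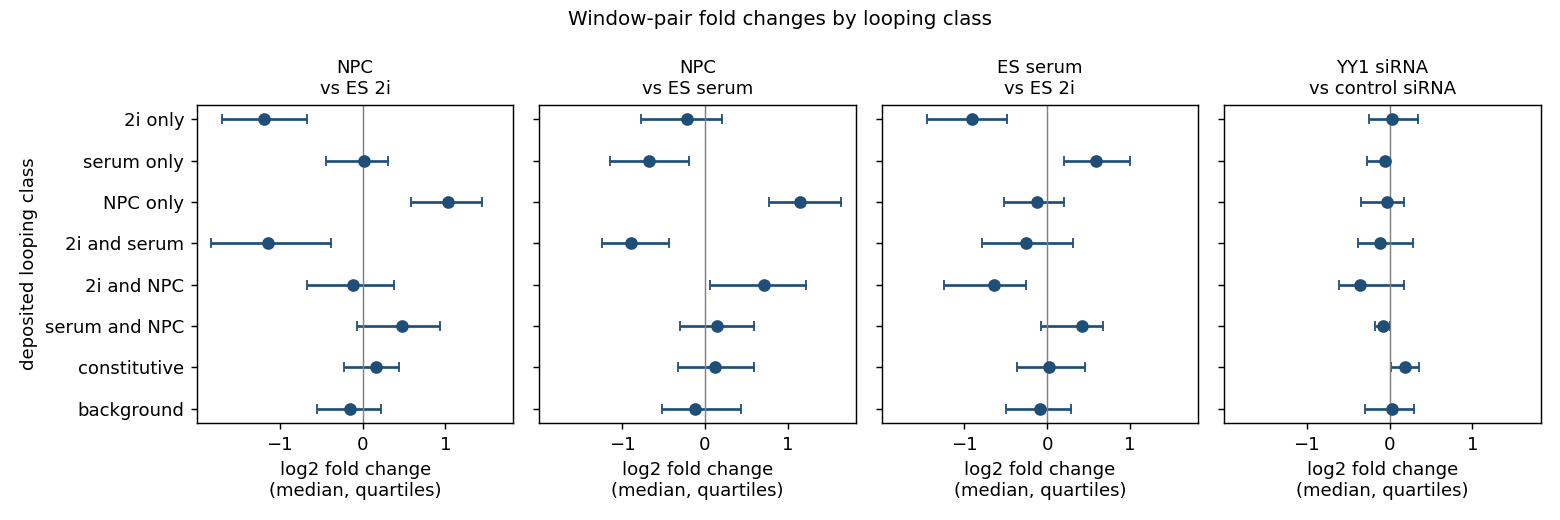
Points give the median log2 fold change of the window pairs of each looping class and bars the quartiles, with 1 panel per comparison. The NPC only class has medians of 1.03 and 1.15 in NPCs against the 2i and serum ES cells, and -0.03 after YY1 siRNA.

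The siRNA experiment asked whether loops of NPCs depend on YY1. NPCs received 20 nM siRNA and were collected after 78 hours. In the Sox2 and Klf4 loci, no window pair passed edgeR's test in the YY1 siRNA libraries against the controls and no looping class passed camera, although DESeq2 called 31 or 37 pairs and fry called classes in some settings. The NPC only class (60 window pairs) had a median log2 fold change of -0.03, the 2i only class (48 pairs) 0.04, the 2i and serum class (25 pairs) -0.11 and the constitutive class (16 pairs) 0.19. The 2i and NPC (12 pairs), serum only (9 pairs) and serum and NPC (3 pairs) classes had -0.35, -0.05 and -0.08, and background (126 pairs) had 0.03.

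YY1 itself was not measured in the data used here, so the extent of the knockdown is unknown. The growth text of the libraries titled as controls also names siRNA against YY1, and the groups follow the titles. Of 3624 pairs, edgeR called 0, with 330 at an unadjusted p below 0.05 and a smallest adjusted p of 0.21, while the DESeq2 counts were 31 with its size factors and 37 with the distance-trend offsets. Replicate 1 of YY1 siRNA, the library with the fewest counts, stood apart. Across window pairs, Pearson's r of corrected log counts was 0.928 between the controls, 0.914 and 0.927 between replicate 2 of YY1 siRNA and the controls, but 0.892 between both YY1 siRNA libraries and 0.882 and 0.885 between replicate 1 and the controls. With edgeR the count was 27 without replicate 2 of YY1 siRNA, 8 without replicate 1 of the controls and 10 without replicate 2 of the controls. By camera every class had an adjusted p of 0.69, and the smallest unadjusted fry p was 0.069, for the NPC only class (fry adjusted p = 0.42). By fry the NPC only class passed in 8 kb windows (adjusted p = 0.049) and without replicate 1 of the controls (adjusted p = 0.035). On simulated counts for this comparison, the same steps recovered 65 of 97 pairs changed by a log2 fold change of 2 and 30 of 99 changed by 1, so most changes of the smaller size would be missed in this comparison. Both sets were changed together among 3585 pairs. With fewer changed pairs the Benjamini-Hochberg threshold is stricter, so recovery of either size could be lower than in the simulation.

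In window counts the NPC only class had a median log2 fold change of -0.03 and a mean of -0.087, with 32 of 60 pairs negative. Camera's direction was downward without passing. The authors' deposited interaction scores of this class were lower after YY1 siRNA. The mean score over its 252 pixels was 27.5 ± 0.57 in the controls and 20.8 ± 3.25 after YY1 siRNA (SD, n = 2 each). The difference was -6.74, with both YY1 siRNA libraries below both controls. In the controls, 2i and serum pixels had a higher mean score (31.6) and constitutive pixels a lower one (24.9). In the untreated NPC libraries, median scores over all loci were 57.7 and 54.7 for NPC only pixels, against 15.5 and 13.6 for 2i and serum pixels. The class names describe the untreated libraries and did not give the order of the control means. Control means of the other classes were 37.0 for serum and NPC, 16.3 for 2i and NPC, 15.3 for serum only, 14.0 for 2i only and 3.51 for background. Means over the Sox2 and Klf4 loci are not directly comparable with medians over all loci. In the Klf4 locus the NPC only score went from 32.7 ± 4.85 to 16.5 ± 0.048 over 27 pixels. In the Sox2 locus it went from 26.9 ± 1.23 to 21.3 ± 3.64 over 225 pixels. Of 24 NPC only loops, 18 had a lower mean score after YY1 siRNA. The 69 constitutive pixels had 24.9 ± 2.92 in the controls and 30.7 ± 1.75 after YY1 siRNA. Here both YY1 siRNA libraries lay above both controls. The NPC only difference was -4.44 without replicate 1 of YY1 siRNA, and the constitutive difference, 5.82 over all libraries, was 3.76 without replicate 1 of the controls.

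Scores of the 12 serum and NPC pixels were 37.0 ± 3.18 and 32.3 ± 0.95. Those of the 33 serum only pixels were 15.3 ± 1.87 and 13.2 ± 0.54. In both classes the libraries were apart over both loci. In the Sox2 locus alone the differences were 1.45 for serum and NPC (3 pixels) and 1.36 for serum only (7 pixels), with overlapping libraries. Over both loci the serum and NPC difference of -4.69 was -2.45 without replicate 2 of the controls, and the serum only difference of -2.17 was -3.50 without replicate 1 and -0.85 without replicate 2 of the controls. Scores of the 2i only (14.0 and 17.5), 2i and serum (31.6 and 26.8), 2i and NPC (16.3 and 18.8) and background pixels (3.51 and 3.90) overlapped between the groups, and the 2i and serum difference of -4.86 was -0.99 without replicate 1 and -8.74 without replicate 2 of YY1 siRNA. The 2i only, 2i and NPC and background differences turned with a library left out. A two-sided exact permutation test of these library means cannot go below p = 0.333, which the NPC only, constitutive, serum only, and serum and NPC classes reached, so no class could pass. Across pixels, Spearman's rho of the scores was 0.453 between the controls and 0.363 between both YY1 siRNA libraries. It was 0.389 and 0.392 between the controls and replicate 2 of YY1 siRNA, and 0.290 and 0.249 between the controls and replicate 1. With medians over pixels in place of means, the constitutive difference was 3.87 and that of the serum and NPC class -4.66, and in both the libraries were no longer apart (exact permutation p = 0.667). That of the serum only class was -5.19 with the libraries still apart (exact permutation p = 0.333), and that of the 2i and NPC class 6.13 with overlapping libraries. The differences between classes were not tested.

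**Figure D3:**
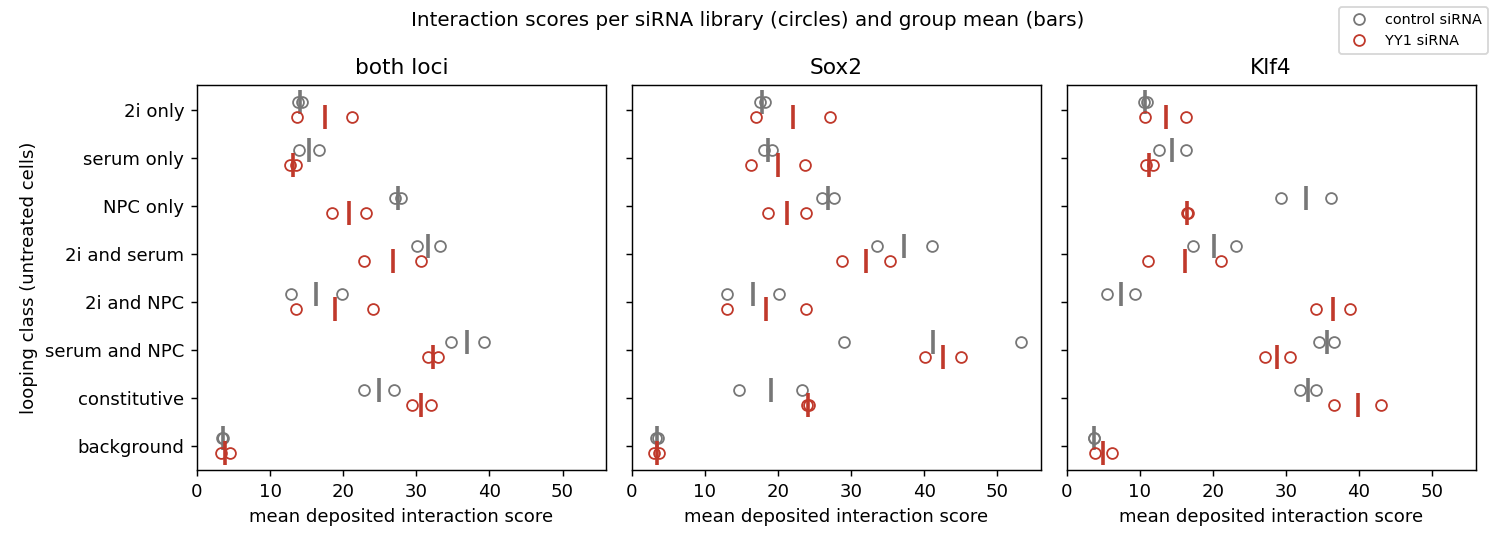
Circles give the mean deposited interaction score of each siRNA library over the pixels of a looping class, and bars the mean of both libraries, for both loci together and for each locus. NPC only pixels lie at 27.1 and 27.9 in the controls and at 18.4 and 23.1 after YY1 siRNA.

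CTCF peaks were fewer in NPCs than in ES cells. The deposited lists held 56138 peaks for ES cells in 2i, 50185 for ES cells in serum and 28860 for NPCs. At an overlap of at least 1 bp with these longer ES lists, 94.7% of NPC peaks overlapped a 2i peak (95% Wilson interval 94.4 to 94.9) and 93.9% a serum peak (93.6 to 94.2). These shares were 75.3% and 65.6% with reciprocal overlap of at least 50%, and 74.6% and 77.4% with equal list sizes. In the other direction, 48.3% of 2i peaks (47.9 to 48.7) and 53.5% of serum peaks (53.1 to 54.0) overlapped an NPC peak. Of 60688 merged regions, 26435 were in all 3 lists, 20068 in both ES lists only and 1119 in the NPC list only.

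Within the 5C loci there were 400, 364 and 196 peaks in the same order. The Oct4 locus held 181 merged regions, 87 of them in all 3 lists, and the Nestin locus 85, with 43 in all 3. In the Sox2 locus 17 of 24 regions and in the Klf4 locus 19 of 26 were in ES lists only, and in the Nanog locus 40 of 63. With 1 library per condition there is no replicate check. When the 28860 peaks with the highest −log10 q were taken from each list, 73.9% of 2i peaks overlapped an NPC peak. Then 5183 regions were in the NPC list only, in place of 1119. This number is the whole NPC list, so only the ES lists were cut, and regions whose ES peaks were cut count as NPC list only. ES sites without an NPC peak were mostly weak. When sites shared by both ES lists were ranked by −log10 q into 10 equal groups, 5.85% of the strongest group had no NPC peak (95% Wilson interval 5.21 to 6.56), against 83.6% of the weakest.

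**Figure D4:**
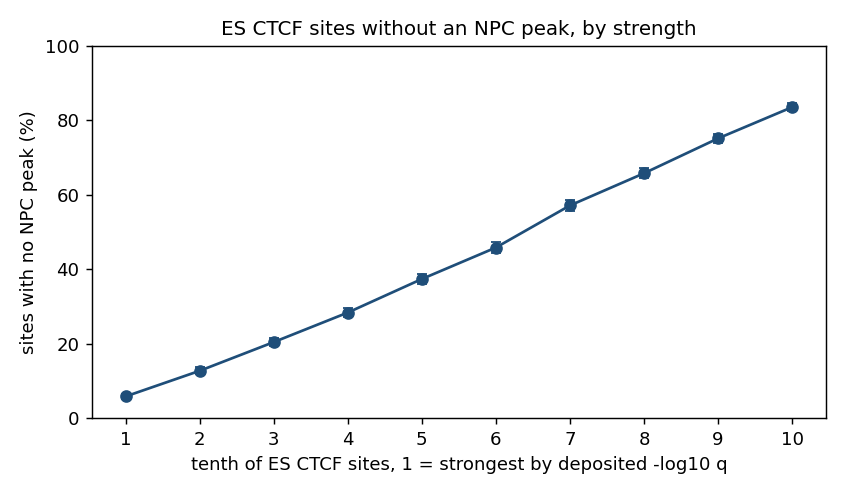
Points give the percent of ES CTCF sites with no NPC peak in each of 10 equal groups ranked by deposited −log10 q, the strongest first, with 95% Wilson intervals. The share goes from 5.85% in the strongest group to 83.6% in the weakest.

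Anchors of several looping classes held CTCF sites more often than after shifting. Sites in ES lists only lay in 17.6% of anchor bins of the 2i only class against 10.8% after shifting peaks along each locus, and in 22.2% against 13.1% for the 2i and serum class. Sites in all 3 lists lay in 15.6% of NPC only anchors against 9.63%, in 18.0% of 2i and NPC anchors against 12.7% and in 16.5% of constitutive anchors against 13.7%. NPC only anchors held sites of the ES lists only in 11.4% against 11.9%.

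In a two-sided test over 10000 shifts the adjusted p was 0.030 for the 2i only class, 0.019 for the 2i and serum class, 0.019 for NPC only and 0.036 for both the 2i and NPC and the constitutive class. The serum and NPC class, with 21.9% of anchors at sites in all 3 lists against 12.9%, had an adjusted p of 0.059. With only peaks of q below 1e-20, which leaves fewer sites, the ES-list calls ended, with 13.9% of 2i only anchors against 8.39% (adjusted p = 0.060) and 15.1% of 2i and serum anchors against 10.4% (adjusted p = 0.15). With bins widened by 1 bin on each side, the 2i and NPC and the constitutive calls ended, with 16.3% against 12.7% and 14.7% against 13.1% (adjusted p = 0.074 and 0.11), and the serum and NPC class passed for sites of the ES lists only, with 20.8% of anchors against 13.03% (adjusted p = 0.024). Differences between classes were not tested.

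**Figure D5:**
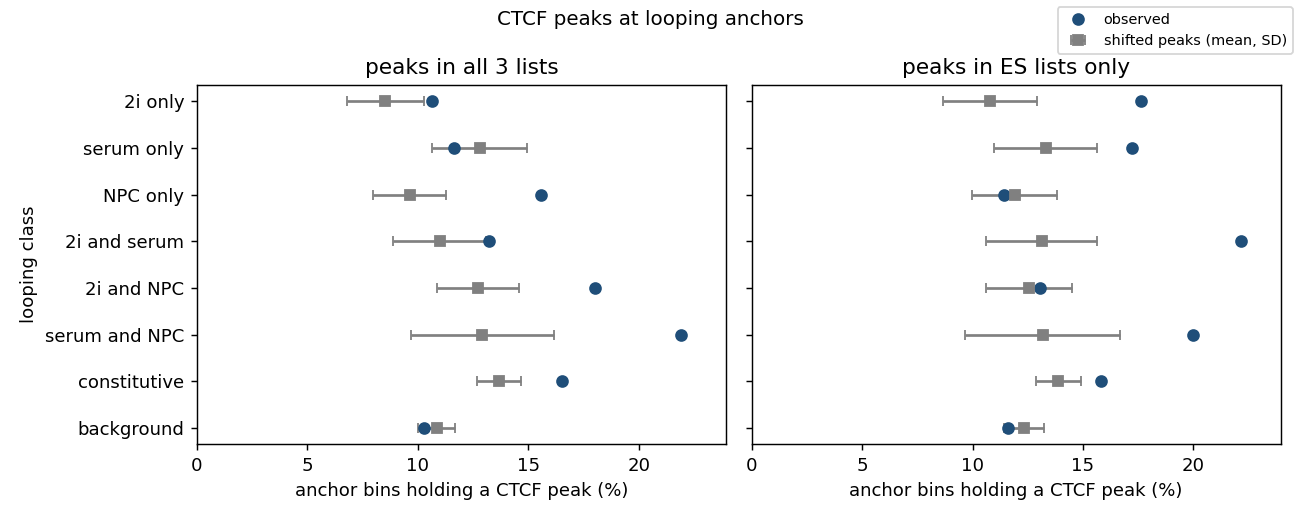
Circles give the percent of 4 kb anchor bins of each looping class that hold a CTCF site, and squares the mean and SD over 10000 shifts of the peaks, for sites in all 3 lists and in the ES lists only. NPC only anchors hold sites of all 3 lists at 15.6% against 9.63% after shifting, and 2i and serum anchors hold ES-list sites at 22.2% against 13.1%.

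Contact counts fell with distance in every library. Over all loci, the slope of log10 mean count on log10 distance from 30 kb to 1 Mb was -0.781 ± 0.039 for ES cells in 2i, -0.774 ± 0.0041 for ES cells in serum and -0.772 ± 0.053 for NPCs (SD, n = 2 each). Over all loci, both serum libraries lay within the range of the 2i libraries and of the NPC libraries. In the Sox2 and Klf4 loci alone, both 2i libraries (-0.767 and -0.691) were steeper than both serum libraries (-0.655 and -0.642), and the NPC libraries lay at -0.698 and -0.637. In these loci the slope was -0.753 ± 0.012 with control siRNA and -0.721 ± 0.038 with YY1 siRNA, with overlapping libraries. From 20 kb to 500 kb over all loci, the slopes of ES cells in 2i, ES cells in serum and NPCs were -0.727, -0.739 and -0.805, with both NPC libraries the steepest. In the Sox2 and Klf4 loci over this range the NPC libraries (-0.706 and -0.735) overlapped the 2i libraries (-0.728 and -0.676). No test was run on the slopes.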

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

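The measurements in this part lie outside the comparisons above and were looked at only after those results were seen. Counts between different loci in the untreated libraries were compared with those expected from each locus' totals over forward and over reverse primers, fitted with counts within a locus left out. The Nestin and Olig1-Olig2 loci, on chromosomes 3 and 16, had the highest ratio of observed to expected counts in all 6 libraries, from 1.31 to 1.60, against 1.17 to 1.27 for the next highest pair of loci. The Sox2 and Nestin loci, both on chromosome 3, had 0.65 to 0.86. Between-locus counts include ligation of unlinked molecules, no library without crosslinking was analysed here, and no biological explanation was tested.

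Primers of the same orientation, which should not be joined by the 5C ligation, gave 0.16% to 0.79% of the counts of the untreated libraries, above 0 in each of them.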

How the results depend on the processing

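The fits on single primer pairs inside class pixels and on thinned counts were chosen after seeing the data, and the other alternatives before. The count of changed window pairs stayed within 1.5 times in 17 of 19 alternatives for NPCs against 2i, 14 of 19 for NPCs against serum and 13 of 19 for serum against 2i. These are counts and not shares of the pairs tested. For NPCs against 2i, the counts in 8 kb windows and over single primer pairs were within 1.5 times. Their shares were 8.79% and 4.21%, against 16.8% in the main fit. Of 1128 results of named window pairs under alternatives, 1006 still passed in the same direction, 122 no longer passed and 0 turned. These pairs were chosen with separated libraries, so with a library left out a turn was nearly excluded beforehand. Results of pairs that a filter removed, or for which DESeq2 gave no adjusted p, are not among the 1128. A group with a library left out keeps 1, which is assumed to vary like the other groups. The siRNA result of 0 pairs held in 9 of 16 alternatives. Where a result changed, the cause was not tested, except that another window width, fewer libraries or fewer peaks change by construction how many features or replicates are tested.

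The counts of changed pairs in 32 kb windows were 1250 for NPCs against 2i, 1677 for NPCs against serum and 1222 for serum against 2i. In 8 kb windows they were 3471, 8334 and 6033 in the same order, and over single primer pairs 3206, 11531 and 7807. With each library left out they ranged from 1220 to 2303 for NPCs against 2i, 2122 to 4261 for NPCs against serum, 840 to 3764 for serum against 2i and 0 to 27 for the siRNA comparison. In the siRNA comparison DESeq2 called 31 pairs with its size factors and 37 with the distance-trend offsets, and a joint fit of all 10 libraries called 2. With plain TMM scaling, 36.4% of Nanog pairs and 38.7% of gene desert pairs changed in NPCs against 2i, and 43.5% of gene desert pairs in NPCs against serum.

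With the replicate number as a block, the counts were 3210, 4937 and 3867 for the untreated comparisons and 4 for the siRNA comparison, in place of 2557, 4319, 3131 and 0. Among classes of the untreated libraries, the block ended fry's call of background in NPCs against serum (adjusted p = 0.065) and gave one of the 2i and serum class in serum against 2i (adjusted p = 0.0255). It moved medians near 0 by over 1.5 times, to 0.0040 for serum only in NPCs against 2i and 0.042 for constitutive in serum against 2i, and after YY1 siRNA to -0.17 for serum only, -0.054 for NPC only and 0.065 for 2i only. Deviations of libraries with the same number had correlations of 0.027, 0.088 and 0.024 in the untreated groups and 0.049 in the siRNA groups, and the labels do not say that a number marks a shared culture or day, so the numbers were not taken to pair the libraries.

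With an estimated correlation, 3 of the 17 camera calls of classes in the untreated libraries remained past the threshold. Median log2 fold changes near 0 turned in some settings. For the serum only class in NPCs against 2i the median was -0.069 with TMM scaling and -0.21 in 8 kb windows, where fry called it (adjusted p = 0.0058), and -0.068 to 0.016 with a library left out. For the constitutive class in serum against 2i it was -0.035, -0.028 and -0.033 to 0.091 in the same settings, and for the serum and NPC class in NPCs against serum -0.019 to 0.19 with a library left out. Fry also called the 2i and NPC class in NPCs against 2i without replicate 2 in 2i (median -0.19, adjusted p = 0.023), the serum and NPC class in NPCs against serum in 8 kb windows and without replicate 2 of NPCs (adjusted p = 0.046 and 0.031), and background in serum against 2i with TMM scaling and without replicate 1 or 2 in 2i (adjusted p = 0.042, 0.0048 and 0.030).

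After YY1 siRNA no class passed camera in any of 9 settings (adjusted p from 0.58 to 0.99), while fry passed in 7 of 72 tests (smallest adjusted p = 0.0074, for the 2i and NPC class without replicate 2 of YY1 siRNA). Medians turned with TMM scaling for the 2i only class (-0.012) and background (-0.018), in 8 kb windows for the serum and NPC class (0.15), and with any pixel counted for the 2i only class (-0.0042) and the serum and NPC class (0.0095). Over single primer pairs they were 0.48 for the serum only class, 0.077 for the 2i and NPC class, -0.043 for the constitutive class and -0.032 for background. Without turning, and apart from the replicate block, medians moved by over 1.5 times with TMM scaling for serum only (-0.15) and NPC only (-0.0033), in 8 kb windows for serum only (-0.21), NPC only (-0.084), 2i only (0.062), constitutive (0.086) and background (0.083), with any pixel counted for 2i and serum (-0.057) and background (0.017), and over single primer pairs for NPC only (-0.078), 2i only (0.0086) and serum and NPC (-0.0041). With a library left out they ranged from -0.036 to 0.094 for the 2i only class, -0.19 to -0.030 for serum only, -0.15 to -0.027 for 2i and serum, -0.18 to 0.038 for NPC only, -0.35 to 0.19 for 2i and NPC, -0.36 to 0.048 for serum and NPC, -0.036 to 0.28 for constitutive and -0.016 to 0.043 for background.

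Differences of deposited scores, YY1 siRNA less control, ranged with a library left out from -0.389 to 7.24 for the 2i only class, -2.79 to 7.75 for 2i and NPC and -0.186 to 0.957 for background. The range was -9.04 to -4.44 for NPC only, -3.50 to -0.85 for serum only, -8.74 to -0.99 for 2i and serum, -6.94 to -2.45 for serum and NPC and 3.76 to 7.89 for constitutive. With the median in place of the mean, the constitutive difference was 3.87 (exact permutation p = 0.667).

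The share of 2i peaks overlapping an NPC peak was 47.0% inside the 5C loci, 45.9% at q below 1e-20, 38.7% with reciprocal overlap and 73.9% with equal list sizes. In the same order, serum peaks overlapped NPC peaks in 51.1%, 50.6%, 37.7% and 76.7%, NPC peaks overlapped 2i peaks in 96.9%, 94.95%, 75.3% and 74.6% and serum peaks in 96.4%, 94.6%, 65.6% and 77.4%, 2i peaks overlapped serum peaks in 85.0%, 83.9%, 81.7% and 86.6%, and serum peaks overlapped 2i peaks in 91.8%, 92.6%, 91.4% and 86.4%.

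At anchors, 5 of 24 tests passed, against 3 of 24 at q below 1e-20 and 4 of 24 with wider bins. With any peak of each list 9 of 16 passed, but these count other, overlapping kinds of site that include those in all 3 lists, so neither that count nor its signs are comparable. Differences from the shifted mean turned for 10 results on the same kinds of site, and any-peak differences had the other sign in 5 more. In percentage points, for ES-list sites at NPC only anchors they were 1.06 at q below 1e-20, 0.255 with wider bins and 5.24 with any ES peak, and at background anchors 0.113 with wider bins. Only 5 merged regions inside the 5C loci were in the NPC list only, so differences for that kind of site rest on few bins. With wider bins, 1 of 369 bins of the 2i only class and 3 of 944 of the constitutive class held such a site. For sites of the NPC list only, wider bins gave differences of -0.0445 for 2i only, -0.0279 for serum only, -0.0697 for 2i and NPC and 0.0254 for constitutive. At q below 1e-20 they were 0.178 for 2i and serum, 0.00653 for constitutive and -0.081 for background, and with any NPC peak -1.10 for serum only, 1.88 for 2i and serum, 2.94 for constitutive and -0.629 for background.

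From 20 kb to 500 kb, distance slopes were -0.727 for ES cells in 2i and -0.739 for ES cells in serum over all loci, and in the Sox2 and Klf4 loci -0.720 for NPCs, -0.773 with YY1 siRNA and -0.787 with control siRNA.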

Other observations

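Of the tests in this part, the one on scores over all looping classes was chosen after its result was seen, and the pairs in the thinned and single-primer tests were chosen after seeing the data, with their bounds set before those tests were run. The further condition that a value lie beyond its bound by more than its spread was set for the single-primer, CTCF strength and thinned tests after their values were known. For the test on scores, an exact p below 0.05 was likewise required only afterwards, which this design cannot reach, and without that requirement its value would have counted against the explanation.

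The density of the looping classes differed between loci, which differ in length, from 192 kb for the gene desert and 732 kb for Nanog to 2096 kb for Oct4. Per 1000 pairs of 4 kb bins, the NPC only class held 7.29 pixels in Sox2, 4.57 in Olig1-Olig2, 3.84 in Nanog and 2.84 in Nestin, against 1.09 in Klf4 and 0.74 in Oct4. The 2i only class held 4.34 in Klf4 and 3.43 in Sox2, against 1.51 in Olig1-Olig2, 0.90 in Nanog, 0.82 in Oct4 and 0.68 in Nestin. The serum only class ranged over the 6 gene loci from 0.23 in Sox2 to 1.95 in Olig1-Olig2, with 1.15 in Oct4. The constitutive class held 7.98 in the gene desert, from 9 pixels among 1128 bin pairs, 7.19 in Nestin, 6.33 in Oct4, 5.04 in Nanog and 3.26 in Olig1-Olig2, against 1.30 in Sox2 and 0.95 in Klf4. No test was run on these densities. Constitutive and 2i and serum pixels joined bins at a median distance of 88 kb, against 240 kb for NPC only, 304 kb for 2i only and 400 kb for serum only pixels. The gene desert held no pixel of the other looping classes.

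NPC only pixels had lower deposited scores in both YY1 siRNA libraries, a difference that no permutation of 2 libraries per group could call. Their summed window counts had a median log2 fold change of -0.03 (mean -0.087) and did not pass camera. Mean scores were higher for 2i only (by 3.42), 2i and NPC (2.48) and constitutive pixels (5.82), and lower in the other looping classes. In the 2i only and the 2i and NPC classes the libraries overlapped, and the difference turned with a library left out. Both YY1 siRNA libraries lay above both controls for constitutive pixels. Among 7 looping classes with 2 libraries per group such an order is easily met by chance, and with medians the constitutive difference was 3.87 and the libraries overlapped. A lower score in every looping class, as a noisier library would give, is thus not excluded. Replicate 1 of YY1 siRNA stood apart, and without it the NPC only difference was -4.44. For the candidate explanation that 16 kb windows dilute a loop of a few 4 kb pixels, single primer pairs inside NPC only pixels had a median log2 fold change of -0.078 (157 primer pairs, standard error of the median 0.087, camera adjusted p = 0.73), which met the bound set against dilution (a median above -0.1 without a call) but by less than its standard error, so dilution is not excluded. A dependence of these loops on YY1, the difference the design names, stays open and is not established with 2 libraries per group and no measure of YY1.

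The NPC list held fewer CTCF peaks than the ES lists. A weaker NPC ChIP library may lose weak peaks first, and the share of ES sites without an NPC peak did go from 5.85% in the strongest of 10 equal groups to 83.6% in the weakest. The bound set for that explanation was under 5% in the strongest group and the bound against it over 20%, so weaker enrichment and a loss of CTCF binding in NPCs cannot be told apart with 1 library per condition. NPC peaks with no ES peak had a median deposited fold enrichment of 10.3, against 15.3 for those with one.

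More window pairs changed between ES cells in serum and in 2i (3131) than between NPCs and ES cells in 2i (2557). The serum libraries were the deepest, and deeper libraries could give more calls. With all 6 libraries thinned to 7158647 counts, the median counts over 10 draws were 2991 and 2557.5. Their ratio was 1.16 (1.14 to 1.18 over the draws), so the number of reads alone does not account for the excess in this fit. Counts are PCR reads without molecular identifiers, so thinning does not equalise distinct ligation products, and a difference in these is not excluded. The excess itself depended on the setting: it turned in 32 kb windows (1222 and 1250 pairs), was nearly absent with DESeq2's size factors (3728 and 3717), under plain scaling (3527 and 3497) and without replicate 1 in 2i (1239 and 1220), and was larger in 8 kb windows (6033 and 3471), with the libraries of both groups alone (3757 and 2002) and over single primer pairs (7807 and 3206). Leaving out a serum library (1261 or 840 against 1969 or 1978) or an NPC library (3764 or 3752 against 2303 or 1985) takes a replicate from only 1 of the comparisons and decides nothing here, and the difference between the comparisons was not tested.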
